A study of Rattus norvegicus with 12 samples.

How the data were processed

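MicroRNA sequencing was done on liver from male Sprague-Dawley rats, an outbred laboratory stock, that were 7 weeks old when dosing by mouth for 5 days began. Per the labels, the rats received vehicle (Control), caffeine at 120 mg/kg (CAF), dextromethorphan at 100 mg/kg (DEX) or both drugs at those doses (CAF+DEX), with 5 rats in each group, and liver was collected 1 h after the last dose. Caffeine is an adenosine receptor antagonist, and dextromethorphan is a cough suppressant that also acts on glutamate and sigma receptors. Libraries from 3 samples per group were deposited, 12 in all. The labels do not tie a library to a rat, so the p-values measure the spread between these samples.

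Small RNA libraries were prepared with a QIAseq kit, whose reverse transcription primer carries unique molecular indices, per the labels' protocols. Whether these indices were collapsed before counting is not given in the sources used here. Trimming with cutadapt 3.7, alignment with STAR 2.7.11b and counting with featureCounts of Subread 2.0.6 on genome build rn7 are named in the submitters' processing notes, without parameters. The deposited values are FPKM, made by the authors, for 444 features, of which 432 are microRNA genes and 12 are of other kinds. Feature lengths ran from 46 to 141 bases, per the file headers. In every library the FPKM multiplied by length in kilobases summed to 1000000, so the authors scaled to reads on the listed features and not to all reads of the library.

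The read totals were recovered from the deposited FPKM. Multiplied by length and by a total for the library, all values came out as multiples of 0.01 read within 2e-05 read, as when a read that maps to several places is shared among them. The totals were 2863572 to 3418568 reads per library, and 50.5 to 58.3% of the features above 0 had whole reads. Precision is limited by the 3 libraries per group and, for rare microRNAs, by counting, and reads need not be independent molecules. No fold is given where both groups average at or under 3 reads. Copies of a microRNA with the same mature sequence share reads, so Mir29b1 and Mir29b-3, Mirlet7c1 and Mirlet7c2, and similar pairs are uncertain as separate features, and each pair counts as 1 signal. The column headers of the deposited table number the libraries within a group (1, 3 and 4 for Control, 1, 2 and 5 for CAF and for CAF+DEX, 1, 2 and 4 for DEX). These numbers are used here as names and could be matched to a group but not to a sample title. Libraries of a group differed by far more than sampling noise (chi-square per degree of freedom 40.4 to 204.7 over 176 features), so none was a copy of another.

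The 293 features above 0 in at least 3 of the 12 libraries, 286 of them microRNAs, were tested. Values were taken as log2(FPKM + 4.01), where 4.01 is the 10th percentile of values above 0, and fold changes on this scale understate the change of rare features. All 12 libraries entered 1 limma-trend model (limma 3.58.1, R 4.3.3) with 4 group means. Its 8 contrasts were the 5 pairwise comparisons, the interaction and the 2 main effects, and a moderated F test covered any difference between the 4 groups. Adjusted p-values are Benjamini-Hochberg values over the 293 features of a contrast, with a threshold of 0.05. Of 20 lists written down, 16 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 16 lists. Of the others, 3 lists of messenger RNAs had 0 members among the features and the list of miR-132 and miR-212 had 2 members. The lists overlap: the inflammation list shares 2 members with the leukocyte list, the p53 and stress list 4 with the hepatocyte list, and the lipid and glucose list 1 with each of the leukocyte, erythroid and stellate lists. The samples' groups, the model, the contrasts, the lists, the filter, the pseudocount rule, the naming rule and the settings listed first in the last paragraph were fixed before the data were examined.

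The naming rule took, for each comparison with Control, all features past the threshold (if no more than 20) and, where fewer than 6 passed, those with the smallest p up to 6 in all. For other contrasts it took the 5 features past the threshold with the largest change or, with none, the 3 with the smallest p. It always added miR-192, miR-21, miR-34a, miR-132 and miR-212, and up to 4 examples per list, the members with the smallest p; miR-122 is not analysed here. Features outside this rule are said to be chosen after their values were seen.

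The test was checked on 20 simulated data sets for CAF against Control with 60 of 293 features changed, at the real depths and spreads. With changed features each under 0.5% of reads, the shares found were 12.3%, 33%, 42.3% and 68.7% for folds of 1.25, 1.5, 2 and 4, and 31.5%, 77.5%, 94.6% and 100% for features averaging at least 100 reads, with 3.7% of calls false. Mir142 and Mir146a, which were called in CAF against Control, took 1.153% and 0.96% of reads, so these shares do not cover features as abundant. In the same simulation with changed features drawn from all abundances, 42.8% of calls were false. Large changes in abundant microRNAs shift the total to which all others are scaled, which may be the reason but was not tested. The restriction to less abundant features was set after that result. With no change, 0.05 features were called on average, and a leukocyte list lowered by 0.5 on the log2 scale was called in 20 of 20 simulations. The other lists were called 3 times in total. These include the inflammation list, with 2 of the lowered members, and the lipid and glucose list, with 1, so the 3 calls need not be false. Features were simulated independently of each other, so members of a list did not vary together. The simulations therefore do not show how often the preset correlation calls unchanged lists whose members vary together. They used the preset correlation only, so they also do not show whether camera with an estimated correlation would find such a lowered list.

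Other settings tried were median-of-ratios scaling, quantile normalization, a smaller pseudocount and one 4 times as large, no filter, a stricter filter, array weights, robust empirical Bayes, microRNA features only, only the 6 samples compared, and leaving out each library. Chosen after the data were seen were limma-voom on the recovered reads, a replicate block on the library numbers of the deposited table, fry for lists, following each list called at the preset correlation through all settings, exact permutations of the means of the 16 lists, an erythroid covariate, the contrast of all treated with control libraries, and the correlation between the 2 caffeine contrasts that share no library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.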

Results

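The data are microRNA abundances in rat liver after 5 days of caffeine, dextromethorphan, both or vehicle, with 3 libraries in each of the 4 groups. The series asks how liver microRNA levels differ after each drug alone and after the combination. The recovered depth was 3103016 to 3418568 reads per library in Control, 2863572 to 3107874 in CAF, 2941725 to 3363795 in DEX and 3145320 to 3360465 in CAF+DEX. Between 258 and 273 features were above 0 in a library. Mir192, a microRNA abundant in hepatocytes (ENSRNOG00000035530, chromosome 1, 203564946 to 203565055, rn7), was the most abundant feature of every library with 14.05 to 16.36% of reads, and the 10 most abundant features took 58.4 to 60.5%. All positions are those of the annotated microRNA gene in the deposited table on rn7; exon, intron or UTR positions in host genes were not analysed here.

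Caffeine alone was compared with vehicle. Mir142, a microRNA of blood cell lineages, fell from 122740 ± 5601 FPKM (SD, n = 3) in Control to 81647 ± 11420 FPKM in CAF. Mir146a, which restrains innate immune signalling, fell from 113700 ± 13710 to 80536 ± 6461 FPKM. The other members of the leukocyte list, Mir342, Mir155, Mir223 and Mir150, were lower too, and in each of the 6 all 3 CAF libraries lay below all 3 Control libraries, a separation that chance gives in 5% of features in this direction and in 10% in either direction for 3 against 3. The 3 erythroid microRNAs, Mir144, Mir451a and rno-mir-486, were also lower in the group mean.

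**Figure D1:**
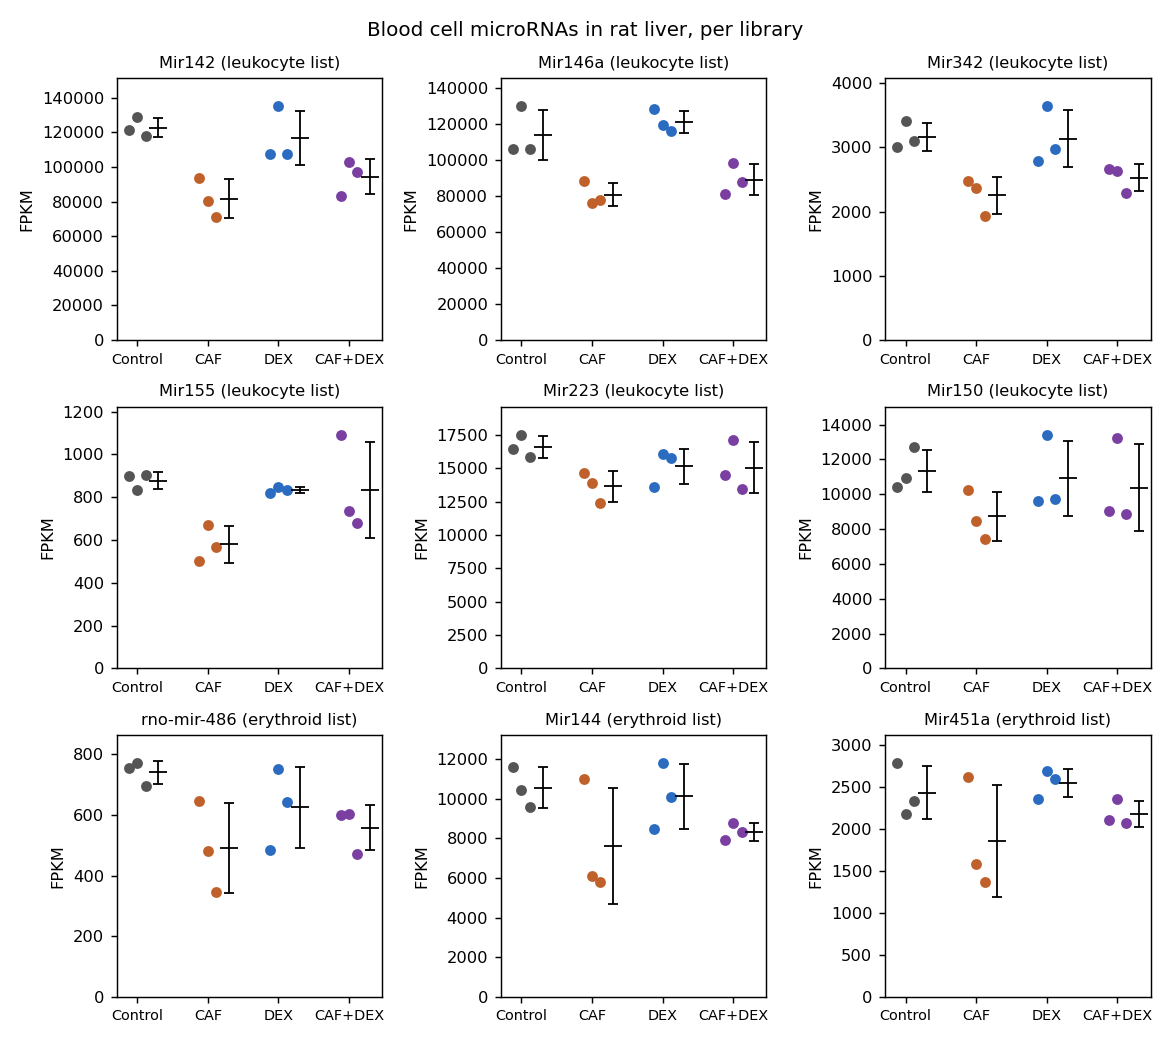
Abundance in FPKM of the 6 leukocyte and 3 erythroid microRNAs, with a point per library, and bars giving the mean ± SD of the 3 libraries of a group. Mir142 averaged 122740 FPKM in Control and 81647 FPKM in CAF, and CAF library 1 lies near the Control libraries for Mir144 and Mir451a.

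Of 293 features tested, 2 passed the threshold in CAF against Control, both lower, and 38 had an unadjusted p under 0.05 where 14.7 are expected by chance. Mir142 (ENSRNOG00000035633, chromosome 10, 72557857 to 72557967) had a log2 fold change of -0.60 (SE 0.12, limma, Benjamini-Hochberg adjusted p = 0.0294). Mir146a (ENSRNOG00000035466, chromosome 10, 27848516 to 27848610) had -0.49 (SE 0.09, limma adjusted p = 0.0294). The next 4 by p did not pass. Mir34c, a p53 target (chromosome 8, 51409726 to 51409802), had -0.79 (SE 0.19, limma adjusted p = 0.09) at a mean of 60.1 reads. Mir342 (chromosome 6, 127565269 to 127565367) had -0.50 (SE 0.12, limma adjusted p = 0.09). Mir29b-3 and Mir29b1, copies of a microRNA that targets collagen transcripts (chromosome 13, 106570367 to 106570456, and chromosome 4, 59650986 to 59651067), had 0.23 (SE 0.06, limma adjusted p = 0.09) and 0.21 (SE 0.05, limma adjusted p = 0.106).

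The leukocyte list was lower in CAF than in Control, with 6 of 6 members lower, a median log2 fold change of -0.50 and 6 members called when adjusted over the list alone, against 2 over all features. Camera gave this list an adjusted p = 1.44e-07 at the preset correlation, and adjusted p = 0.0794 with an estimated correlation. In the erythroid list 3 of 3 members were lower, with a median of -0.53 and 3 called when adjusted over the list alone; camera gave adjusted p = 0.02, and adjusted p = 0.401 with an estimated correlation. This list no longer passed without Control library 1 (camera adjusted p = 0.0643), CAF library 2 (0.0701) or CAF library 5 (0.0982), nor with quantile normalization (0.0928), and its median was -0.82 without CAF library 1. Rno-mir-486 had -0.63 (SE 0.22), Mir144 -0.53 (SE 0.20) and Mir451a -0.44 (SE 0.19). Erythroid levels were uneven within CAF, where library 1 had a mean of -0.01 against the Control mean on the log2 scale and libraries 2 and 5 had -0.67 and -0.92, while the leukocyte means were -0.37, -0.44 and -0.62.

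The other 14 lists did not pass in CAF against Control. Medians were 0.03 for 11 hepatocyte microRNAs, 0.01 for 9 let-7 members, -0.08 (mean -0.23) for 9 regulators of cytochrome P450 and nuclear receptor transcripts, 0.01 for 7 p53 and stress microRNAs and -0.01 for 11 lipid and glucose microRNAs. The stress list's mean was -0.23, against the sign of its median, with Mir34c and Mir34b, at -0.67 (SE 0.29), its lowest members. In the lipid and glucose list the mean was 0.06, and 5 members were called when adjusted over the list alone. They were both miR-29b copies, which share reads and give 1 signal, Mir802 at 0.36 (SE 0.10), Mir223 at -0.29 (SE 0.10) and Mir144. The last 2 also stand in the leukocyte and erythroid lists. Medians were -0.20 for 8 inflammation microRNAs, 0.11 for 16 of the miR-17-92 family, 0.07 for 4 of the miR-183 and clock list and 0.06 for 19 of the imprinted Dlk1-Dio3 cluster. Markers of other cells and tissues had medians of 0.03 in endothelium, 0.17 in stellate and mesenchymal cells, -0.06 in biliary epithelium, -0.80 in 4 muscle microRNAs and 0.03 in neurons and pancreas. Means differed in sign from medians also for the let-7 (-0.03), miR-17-92 (-0.02), miR-183 and clock (-0.14) and neuron and pancreas (-0.03) lists. Mir192 had a log2 fold change of 0.01 (SE 0.06), Mir21 0.04 (SE 0.11), Mir34a -0.24 (SE 0.18; -0.04 without Control library 3, -0.13 without CAF library 1 and -0.43 without CAF library 5) and Mir132, at a mean of 6.67 reads, -0.91 (SE 0.39; -0.52 without CAF library 1). Mir212 averaged 0.92 reads and is given no fold.

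The 2 calls in CAF against Control became 0 without Control library 1, Control library 3, CAF library 2 or CAF library 5, 1 without DEX library 2, 4 without CAF+DEX library 1, 5 without Control library 4 and 10 without CAF library 1. They also became 0 with no filter and in a fit of only the 6 samples compared, 4 with quantile normalization and 6 with the stricter filter.

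**Figure D2:**
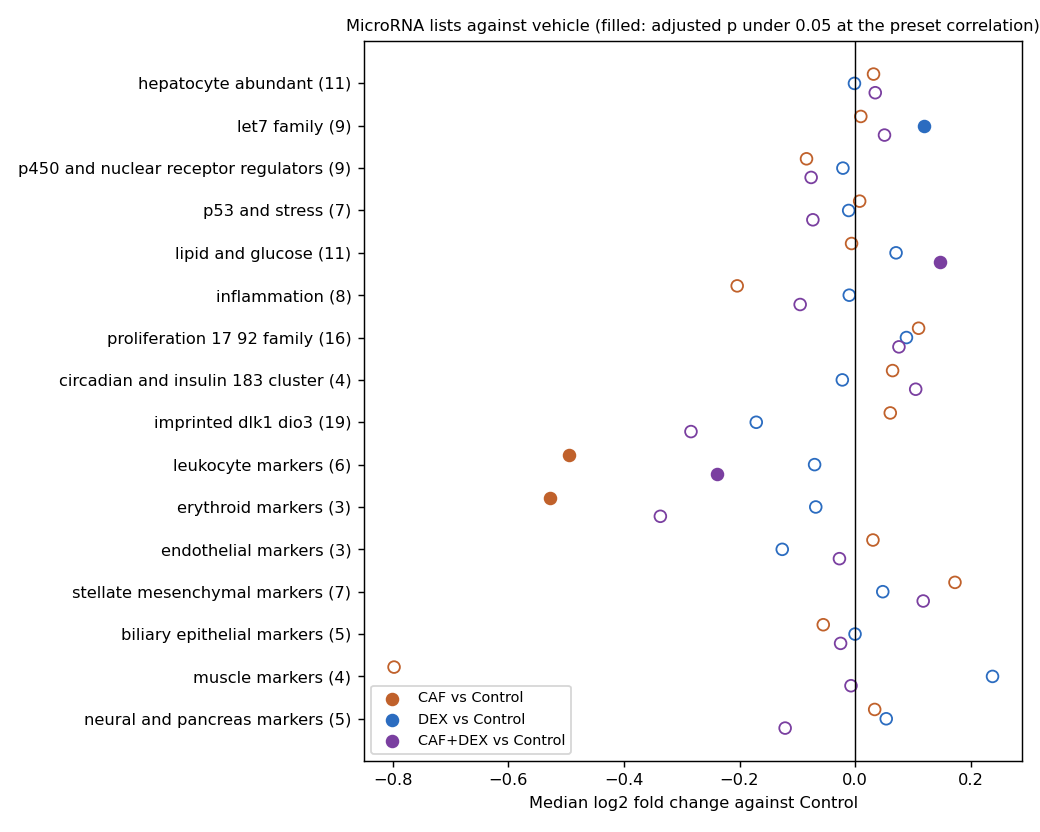
Median log2 fold change against Control for each of the 16 lists, with the number of tested members in parentheses and a point for CAF, DEX and CAF+DEX; filled points have a camera adjusted p under 0.05 at the preset correlation, and none does with an estimated correlation. The leukocyte list lies at -0.50 in CAF, -0.07 in DEX and -0.24 in CAF+DEX.

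Dextromethorphan alone was compared with vehicle. No microRNA passed the threshold, and the leukocyte microRNAs lay near the Control level, with a median log2 fold change of -0.07. The 9 let-7 members, which act in differentiation and growth control, were all higher with a median of 0.12, and Mirlet7d stood at 0.18 (SE 0.06, n = 3 per group). Mir29b1 and Mir29b-3 had 0.20 (SE 0.05) and 0.20 (SE 0.06).

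In limma, 0 of 293 features passed in DEX against Control and 13 had an unadjusted p under 0.05, where 14.7 are expected; limma-voom also called 0. Mir190b (chromosome 2, 175514800 to 175514877) had the smallest p, with -0.61 (SE 0.15, limma adjusted p = 0.312). Mir20a had 0.23 (SE 0.08), and Mir494 averaged 3.33 reads in Control and 0.67 in DEX. The let-7 list had a camera adjusted p = 0.000448 at the preset correlation and adjusted p = 0.825 with an estimated correlation. When adjusted over the list alone, 0 of its members were called, and its copies Mirlet7c1 and Mirlet7c2 share reads. Its median fell to 0.08 without Control library 1. Its preset p rose to 0.0669 without DEX library 4 and 0.0933 with quantile normalization, and 1 feature, Mir190b, was called without Control library 3. The other 15 lists did not pass; in the imprinted cluster 12 of 19 members were lower with a median of -0.17. Mir192 had -0.11 (SE 0.06), Mir21 0.01 (SE 0.11), Mir34a -0.21 (SE 0.18; -0.01 without Control library 3, -0.13 without DEX library 2, -0.32 without Control library 1 and -0.31 without DEX library 4) and Mir132 0.00 (SE 0.39).

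Both drugs together were compared with vehicle. Mir142 stood at 94348 ± 10150 FPKM (SD, n = 3) in CAF+DEX and Mir146a at 88830 ± 8703 FPKM, both between the CAF and Control means. The 6 leukocyte microRNAs were all lower, with a median log2 fold change of -0.24, and in 3 of the 6 all CAF+DEX libraries lay below all Control libraries. Mir29b-3 and Mir29b1 had the smallest p, at 0.25 (SE 0.06) and 0.24 (SE 0.05).

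In limma, 0 of 293 features passed in CAF+DEX against Control and 30 had an unadjusted p under 0.05, where 14.7 are expected; limma-voom also called 0, quantile normalization 1 and the stricter filter 2. The limma adjusted p was 0.0906 for both miR-29b copies, 0.252 for Mir146a at -0.35 (SE 0.09) and 0.351 for Mir142 at -0.38 (SE 0.12). Mir322-2 (chromosome X, 132806594 to 132806688) had 0.22 (SE 0.07) and Mir130b (chromosome 11, 83880163 to 83880244) -0.87 (SE 0.29). Camera called 2 lists at the preset correlation. The leukocyte list had adjusted p = 0.00129, and adjusted p = 0.256 with an estimated correlation, with 3 members called when adjusted over the list alone. The lipid and glucose list, 8 of 11 members higher with a median of 0.15, had a camera adjusted p = 0.0187, and adjusted p = 0.256 with an estimated correlation. Its 3 members called when adjusted over the list alone were both miR-29b copies and Mir802 at 0.28 (SE 0.10). The copies share reads, so this list counts 1 signal as 2 members. The lipid and glucose list no longer passed without CAF+DEX library 2 (median 0.095, camera adjusted p = 0.114), with quantile normalization (0.264) or with the stricter filter (0.1). In the erythroid list 3 of 3 members were lower with a median of -0.34 (camera adjusted p = 0.155). All 7 p53 and stress microRNAs were lower with a median of -0.07, among them Mir34a at -0.52 (SE 0.18; -0.31 without Control library 3). Mir192 had -0.07 (SE 0.06), Mir21 -0.05 (SE 0.11) and Mir132 0.49 (SE 0.39; 0.20 without CAF+DEX library 1).

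Adding dextromethorphan to caffeine was compared with caffeine alone. No microRNA passed the threshold. The 6 leukocyte microRNAs were all higher in CAF+DEX than in CAF, with a median log2 fold change of 0.19, led by Mir155 at 0.50 (SE 0.17, n = 3 per group; 0.29 without CAF+DEX library 1). In the imprinted Dlk1-Dio3 cluster 14 of 19 members were lower with a median of -0.41, among them Mir376b at -0.51 (SE 0.21) and Mir136 at -0.73 (SE 0.30).

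In limma, 0 of 293 features passed in CAF+DEX against CAF and 15 had an unadjusted p under 0.05, where 14.7 are expected; limma-voom also called 0. Mir132 had the smallest p, with 1.40 (SE 0.39, limma adjusted p = 0.88), from 3.0 reads in CAF and 10.33 in CAF+DEX. Mir323 averaged 1.17 reads and is given no fold. Camera gave the leukocyte and imprinted lists each an adjusted p = 0.00147 at the preset correlation, and an adjusted p = 0.389 each with an estimated correlation, with 0 members of either called when adjusted over the list alone. The imprinted list no longer passed without CAF library 2 (median -0.13) or CAF+DEX library 5 (median -0.08), and the leukocyte list no longer passed without CAF library 5 (median 0.11), without CAF+DEX library 2 (median 0.10) or with quantile normalization (median 0.12). Mir192 had -0.08 (SE 0.06), Mir21 -0.09 (SE 0.11) and Mir34a -0.27 (SE 0.18; -0.09 without CAF library 5).

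Adding caffeine to dextromethorphan was compared with dextromethorphan alone, with no library in common with CAF against Control. Mir146a was lower at 88830 ± 8703 FPKM (SD, n = 3) in CAF+DEX against 121140 ± 6066 FPKM in DEX, without passing the threshold. All 6 leukocyte microRNAs were lower with a median log2 fold change of -0.19, and Mir142 and Mir342 each had -0.31 (SE 0.12). Mir155 and Mir223, chosen after their values were seen, lay near 0, at -0.03 (SE 0.17) and -0.01 (SE 0.10).

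In limma, 0 of 293 features passed in CAF+DEX against DEX and 23 had an unadjusted p under 0.05, where 14.7 are expected; limma-voom also called 0, and 1 was called with quantile normalization, without Control library 3 or without DEX library 4. Mir146a had -0.45 (SE 0.09, limma adjusted p = 0.119). Mir218-2 (chromosome 10, 20068451 to 20068560) had 0.47 (SE 0.14) and rno-mir-335 (chromosome 4, 59357769 to 59357866) 0.31 (SE 0.10; 0.21 without DEX library 1). The leukocyte list had a camera adjusted p = 0.0431 at the preset correlation and adjusted p = 0.693 with an estimated correlation, with 1 member called when adjusted over the list alone. This list no longer passed without DEX library 2 or CAF+DEX library 5 (median -0.11 each), and also not without Control library 1 (camera adjusted p = 0.0537), Control library 4 (0.0533), CAF library 2 (0.0557) or DEX library 4 (0.0542), nor with the larger pseudocount (0.0526); without CAF+DEX library 2 its median was -0.30. Erythroid microRNAs were lower in 3 of 3 with a median of -0.23 (camera adjusted p = 0.527). Mir192 had 0.04 (SE 0.06), Mir21 -0.07 (SE 0.11), Mir34a -0.31 (SE 0.18; -0.20 without DEX library 4) and Mir132 0.49 (SE 0.39; 0.20 without CAF+DEX library 1).

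**Figure D3:**
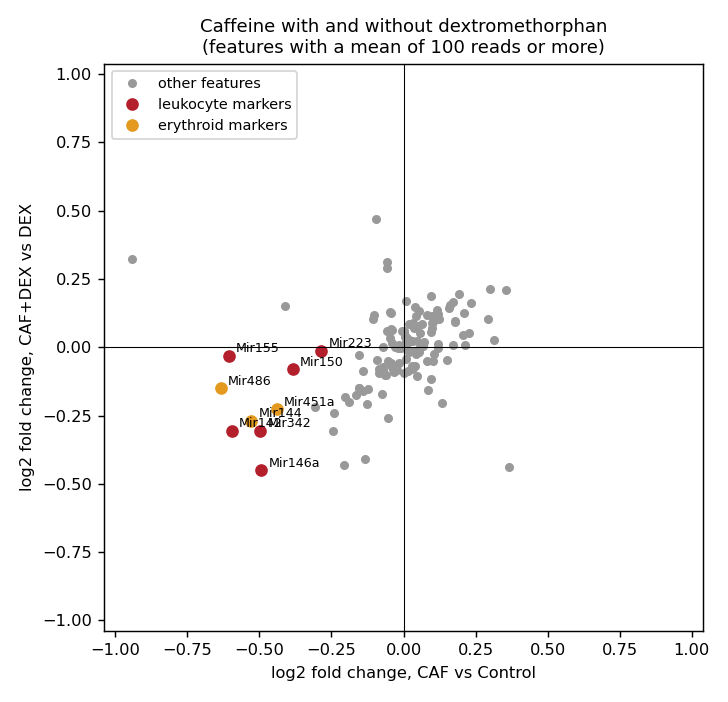
Log2 fold change of CAF against Control (horizontal) and of CAF+DEX against DEX (vertical) for the 135 features averaging at least 100 reads, a point per feature, with leukocyte and erythroid microRNAs in color. The leukocyte microRNAs lie below 0 on both axes, and the correlation is 0.355 across these features and 0.023 across all 293.

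The interaction asked whether the drugs together differed from the sum of each alone on the log2 scale. No single microRNA passed. The 6 leukocyte microRNAs all had positive interactions with a median of 0.28. As a set, their difference between caffeine and no caffeine was smaller where dextromethorphan was given. Mir146a, chosen after its value was seen, had an interaction of only 0.04 (SE 0.13). Its caffeine difference was -0.49 without dextromethorphan and -0.45 with it. Mir136, of the imprinted cluster, had the smallest p with -1.37 (SE 0.43), from a log2 fold change of 0.64 (SE 0.30) in DEX against Control and -0.73 (SE 0.30) in CAF+DEX against CAF.

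In limma, 0 of 293 features passed the interaction and 16 had an unadjusted p under 0.05, where 14.7 are expected; limma-voom also called 0, and 1 feature was called without DEX library 4. The limma adjusted p was 0.835 for Mir136, for Mir320a at -0.80 (SE 0.29), for Mir218-2 at 0.56 (SE 0.20) and for Mir132 at 1.40 (SE 0.55). The leukocyte list had a camera adjusted p = 0.00923 at the preset correlation and adjusted p = 0.674 with an estimated correlation, with 0 members called when adjusted over the list alone. Its preset p was 0.213 without CAF library 5, 0.143 without DEX library 1, 0.0637 without CAF+DEX library 2 (median 0.17) and 0.0629 without Control library 3, and 0.0971 with quantile normalization. Mir192 had 0.03 (SE 0.09), Mir21 -0.11 (SE 0.16) and Mir34a -0.06 (SE 0.25).

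The main effect of caffeine set the 6 libraries with caffeine against the 6 without. Mir146a fell by 0.47 on the log2 scale (SE 0.07, limma, Benjamini-Hochberg adjusted p = 0.00314), and Mir142 fell by 0.45 (SE 0.08, limma adjusted p = 0.0163). All 6 leukocyte microRNAs were lower with a median of -0.36, Mir342 at -0.40 (SE 0.09) and Mir155 at -0.32 (SE 0.12). All 3 erythroid microRNAs were lower with a median of -0.39.

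Of 293 features, 2 passed the caffeine main effect, both lower, and 43 had an unadjusted p under 0.05, where 14.7 are expected. The leukocyte list had a camera adjusted p = 2.8e-06 at the preset correlation and adjusted p = 0.135 with an estimated correlation, with 4 members called when adjusted over the list alone. The erythroid list had adjusted p = 0.0426, and adjusted p = 0.445 with an estimated correlation, with 3 called when adjusted over the list alone. The erythroid list no longer passed without Control library 1, CAF library 2, CAF library 5, DEX library 2, DEX library 4, CAF+DEX library 2 or CAF+DEX library 5, where the highest camera adjusted p was 0.112, nor with quantile normalization (0.184), the larger pseudocount (0.0524) or the stricter filter (0.0845). Mir192 had 0.02 (SE 0.04), Mir21 -0.01 (SE 0.08), turning to 0.01 with median-of-ratios scaling, Mir34a -0.28 (SE 0.13; -0.18 without Control library 3) and Mir132 -0.21 (SE 0.27; -0.01 without CAF library 1, -0.12 without DEX library 4, -0.36 without CAF+DEX library 1 and -0.10 without CAF+DEX library 2). The calls became 10 without CAF library 1, 8 without CAF+DEX library 1, 6 without CAF+DEX library 2 and 1, Mir146a, without Control library 3 or CAF library 2. They were 4 with limma-voom, 5 with quantile normalization, 6 with robust empirical Bayes, 8 with array weights, 10 with the stricter filter and 11 with median-of-ratios scaling.

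The main effect of dextromethorphan set the 6 libraries with it against the 6 without. No microRNA passed the threshold. The 9 let-7 members were all higher with a median log2 fold change of 0.11, Mirlet7d at 0.11 (SE 0.04) and Mirlet7b at 0.13 (SE 0.06). In the imprinted Dlk1-Dio3 cluster 16 of 19 were lower with a median of -0.25. Its members were mostly less abundant features, and the stricter filter dropped the list from testing.

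In limma, 0 of 293 features passed the dextromethorphan main effect and 22 had an unadjusted p under 0.05, where 14.7 are expected; limma-voom also called 0. Mir362 (chromosome X, 15254615 to 15254679) had 0.26 (SE 0.08) and Mir29b1 0.12 (SE 0.04), both with a limma adjusted p = 0.497. The let-7 list had a camera adjusted p = 0.000144 and the imprinted list 0.000457 at the preset correlation; with an estimated correlation these were adjusted p = 0.531 and adjusted p = 0.528, and 0 members of either were called when adjusted over the list alone. The imprinted list no longer passed without CAF library 2 (median -0.15, camera adjusted p = 0.0518) or CAF+DEX library 5 (0.0672), its median was -0.39 without CAF library 1, and the let-7 list no longer passed with quantile normalization (0.0507). Mir192 had -0.10 (SE 0.04), Mir21 -0.04 (SE 0.08), Mir34a -0.24 (SE 0.13; -0.14 without Control library 3 and -0.15 without CAF library 5) and Mir132 0.70 (SE 0.27).

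Over any difference between the 4 groups, the limma F test called 1 feature, Mir146a (adjusted p = 0.0255), and Mir142 had an adjusted p = 0.0977; 33 features had an unadjusted p under 0.05, where 14.7 are expected. This call was lost with no filter and without CAF library 2, CAF library 5, DEX library 1, DEX library 2 or CAF+DEX library 5, and the count was 4 without CAF library 1 and 2 without DEX library 4 or CAF+DEX library 1. Across the 293 features the log2 fold changes of CAF and of DEX against the shared Control libraries had a Pearson correlation of 0.394. Simulations shuffled the deviations from the group means of all 12 libraries into groups with no effect, 1 of them a shared control. The real Control libraries were not held fixed. The simulations gave a median of 0.491, and 70 of 100 lay at or above the observed value. The covariance was 0.053 against 0.0654 simulated. Features are not independent replicates, and the 3 controls are too few to be split with 2 in each part. In these simulations a shared control group alone gave correlations of this size, so the observed value is no sign of a common response. With the preset correlation, regroupings of the same libraries called as many lists in 36 of 100 splits for the caffeine main effect and 40 of 100 for dextromethorphan. The counts of called lists for these main effects did not exceed those of chance splits. For the interaction it was 68 of 100, but those splits also mix libraries with and without caffeine and do not measure chance for the interaction alone. With an estimated correlation, which the simulations of the lowered leukocyte list did not use, 0 lists passed in any contrast.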

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

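The exact permutation of the list mean was a test chosen after the result was seen. The caffeine difference of the leukocyte list (Mir146a, Mir142, Mir342, Mir155, Mir223 and Mir150) differed between rats with and without dextromethorphan by the list's own interaction test at the preset correlation (camera adjusted p = 0.00923), but not with an estimated correlation (adjusted p = 0.674). The median interaction was 0.281 on the log2 scale, with 6 of 6 members positive, and the mean of the 6 differed by -0.477 with caffeine alone and by -0.198 with caffeine in the presence of dextromethorphan. Mir146a, chosen after its value was seen, had an interaction of only 0.043 (SE 0.133).

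Leaving out CAF library 5, DEX library 1, CAF+DEX library 2 or Control library 3 raised the camera adjusted p to 0.213, 0.143, 0.0637 and 0.0629, while the median interaction stayed positive at 0.195, 0.208, 0.166 and 0.244, and over the settings other than leave-one-out the p ran from 0.00429 to 0.0971. The mean interaction of the 6 was 0.279 (SE 0.128) with all libraries and 0.210 (SE 0.121) without CAF library 5, so the lost call neither shows nor rules out that 1 library is the source. Members that vary together between libraries may also account for the small preset p, since an exact two-sided permutation of the list mean over 400 relabellings gave p = 0.07 with dextromethorphan labels permuted and p = 0.305 with caffeine labels permuted, where 0.005 is the smallest possible; regulators of cytochrome P450 and nuclear receptor transcripts, not called by camera, had smaller p of 0.01 and 0.1 with a mean interaction of 0.183. In 68 of 100 splits of the 12 libraries, the real one included, the interaction called at least as many lists as the real 1, up to 5. Those splits mix libraries with and without caffeine, so the share does not measure chance for the interaction alone, and chance is not excluded. An attenuation of the caffeine response by dextromethorphan, the biological reading the design offers, stays open and untested beyond these values.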

How the results depend on the processing

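The planned replicate block on the numbers of the sample titles was not run, since the library numbers in the deposited table do not match those titles. A replicate block on the library numbers themselves was added after the data were seen. Nothing in the labels says that a number marks a shared litter, batch or day, and same-numbered libraries of different groups did not deviate together: over 11 such pairs the correlation of deviations from the group means ran from -0.126 to 0.105, against -0.176 to 0.248 over 43 pairs of different numbers, and 0 of 11 libraries correlated best with their own number. These pairs gave no sign of a shared factor, but so few cannot exclude one that acts on part of the features. Number 3 occurs only in Control library 3, so the block fits that library exactly and it adds nothing to the contrasts. With this block, which leaves 4 residual degrees of freedom, calls were 0 in CAF against Control, 0 for the caffeine main effect, 0 for the F test and 1, Mir190b, in DEX against Control (-0.813, limma adjusted p = 0.0392), with 0 in the other contrasts. Mir146a had -0.407 (limma adjusted p = 0.306) and Mir142 -0.631 (0.158) in CAF against Control, and -0.430 (0.228) and -0.473 (0.252) for caffeine. Called lists were 2 in CAF against Control, 3 in DEX against Control, 3 in CAF+DEX against Control, 2 in CAF+DEX against CAF, 0 in CAF+DEX against DEX and 2 each for the interaction and both main effects. The leukocyte list was called in each contrast where it was without the block except CAF+DEX against DEX (median -0.117, camera adjusted p = 0.171), the erythroid list was not called (0.11 and 0.165), and called with the block only were muscle markers in CAF against Control and for caffeine (medians -1.341 and -1.196), the miR-17-92 family in DEX against Control and the interaction, the imprinted list in DEX against Control and let-7 in CAF+DEX against Control.

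DESeq2 was not run because the reads recovered from the FPKM include fractions of reads and are not whole counts. The cause of the changes given here was not tested, except that a stricter filter, no filter, the fit of 6 samples and leave-one-out change the number of features or samples by construction. Mir146a passed for the caffeine main effect in 23 of 23 settings and Mir142 in 21; for CAF against Control they passed in 17 and 18 of 23, and neither passed in the fit of only the 6 samples, which like the block is not among the 23 (limma adjusted p = 0.0985 and 0.0793). The leukocyte list kept its preset call in every setting that gives list values (robust empirical Bayes and the fit of 6 samples give none) for CAF against Control (median -0.508 to -0.428 outside leave-one-out and the block), CAF+DEX against Control and the caffeine main effect, but not with an estimated correlation (adjusted p = 0.0794, adjusted p = 0.256 and adjusted p = 0.135). No scaling moved the median of all features by over 0.1. Depth limits Mir132 and Mir212, which average 6.67 and 0.92 reads; no fold of Mir212 or Mir323, at or under 3 reads in each group compared, was followed. Limma-voom was chosen after the data were seen.

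Calls for the caffeine main effect, 2 as reported, were 11 with median-of-ratios scaling, 5 with quantile normalization, 10 with the stricter filter, 8 with array weights, 6 with robust empirical Bayes and 4 with limma-voom. Calls in CAF against Control, 2 as reported, were 4 with quantile normalization, 6 with the stricter filter, and 0 with no filter or only the 6 samples. CAF+DEX against Control, at 0, had 1 with quantile normalization and 2 with the stricter filter, and CAF+DEX against DEX, at 0, had 1 with quantile normalization. The F test's 1 call became 0 with no filter and 2 with array weights. Called lists became, with quantile normalization, 1 in CAF against Control, CAF+DEX against Control, CAF+DEX against CAF and both main effects, and 0 in DEX against Control and the interaction. With 4 times the pseudocount they were 0 in CAF+DEX against DEX and 1 for the caffeine main effect. With no filter DEX against Control had 3. With the stricter filter CAF+DEX against Control, CAF+DEX against CAF and both main effects had 1. There the imprinted list had fewer than 3 members left and was not tested in CAF+DEX against CAF and the dextromethorphan main effect. With array weights DEX against Control had 2 and the dextromethorphan main effect 4.

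Lists that lost their preset call, by median, were with quantile normalization the leukocyte list in the interaction (0.262) and in CAF+DEX against CAF (0.117), the erythroid list in CAF against Control (-0.421) and the caffeine main effect (-0.299), let-7 in DEX against Control (0.077) and the dextromethorphan main effect (0.049), and the lipid and glucose list in CAF+DEX against Control (0.071), which was also lost with the stricter filter (0.109). With 4 times the pseudocount they were the leukocyte list in CAF+DEX against DEX (-0.193) and the erythroid caffeine main effect (-0.385), which was also lost with the stricter filter (-0.393). Outside leave-one-out, the directions that reversed, all of values that did not pass, were Mir21 in the caffeine main effect (0.007, median-of-ratios) and Mir34a in the interaction (0.005, quantile).

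Leaving out each library in turn, calls ranged from 0 to 10 in CAF against Control, 1 to 10 for the caffeine main effect, 0 to 4 for the F test and 0 to 1 for DEX against Control, CAF+DEX against DEX and the interaction. Called lists ranged from 1 to 4 in CAF against Control, 0 to 2 in DEX against Control, CAF+DEX against DEX and the interaction, 1 to 5 in CAF+DEX against Control and the dextromethorphan main effect, and 1 to 3 in CAF+DEX against CAF and the caffeine main effect. Medians ranged from -0.303 to -0.106 for leukocytes in CAF+DEX against DEX, 0.166 to 0.359 for the leukocyte interaction, 0.102 to 0.278 for leukocytes in CAF+DEX against CAF, 0.095 to 0.205 for the lipid and glucose list in CAF+DEX against Control, -0.824 to -0.363 and -0.502 to -0.280 for the erythroid list in CAF against Control and the caffeine main effect, 0.079 to 0.152 for let-7 in DEX against Control, and -0.561 to -0.081 and -0.386 to -0.149 for the imprinted list in CAF+DEX against CAF and the dextromethorphan main effect. Of single features, Mir192 ranged from -0.027 to 0.072 in the interaction, -0.018 to 0.044 in CAF against Control, -0.018 to 0.080 in CAF+DEX against DEX, -0.131 to -0.033 in CAF+DEX against Control, -0.139 to -0.041 in CAF+DEX against CAF and -0.005 to 0.044 for caffeine. Mir21 ranged from -0.058 to 0.066 in DEX against Control, -0.091 to 0.039 for caffeine, -0.116 to 0.013 for dextromethorphan, -0.221 to 0.038 in CAF+DEX against DEX, -0.207 to 0.052 in CAF+DEX against Control, -0.247 to 0.012 in CAF+DEX against CAF, 0.002 to 0.070 in CAF against Control and -0.262 to -0.002 in the interaction. Mir34a ranged from -0.266 to 0.117 in the interaction, -0.425 to -0.042 in CAF against Control, -0.317 to -0.005 in DEX against Control and -0.625 to -0.312 in CAF+DEX against Control, nearest 0 without Control library 3 in these 3 comparisons, and from -0.386 to -0.090 in CAF+DEX against CAF, -0.382 to -0.201 in CAF+DEX against DEX, -0.366 to -0.175 for caffeine and -0.297 to -0.138 for dextromethorphan. Mir132 ranged from -1.118 to -0.515 in CAF against Control, 0.199 to 0.706 in CAF+DEX against Control and against DEX, -0.166 to 0.122 in DEX against Control and -0.355 to -0.010 for caffeine. Mir155 ranged from 0.293 to 0.634 in CAF+DEX against CAF.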

Other observations

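The tests chosen after the result was seen are the erythroid covariate, the comparison of cell type lists in CAF+DEX against DEX, the exact permutations of list means, the split counts of the leukocyte list's p, the contrast of all treated with control libraries and the correlation between the caffeine contrasts that share no library.

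Behind the 2 calls of the caffeine main effect stood 8 features that missed the threshold narrowly, each with a limma adjusted p = 0.0525, 4 higher and 4 lower; they were chosen after their values were seen. Those lower with caffeine were Mir342 at -0.40 (SE 0.09), Mir15b at -0.24 (SE 0.06), Mir20b at -0.65 (SE 0.16) and Mir187 at -0.71 (SE 0.17). Those higher were Mir802, a liver microRNA linked to glucose handling, at 0.28 (SE 0.07), Mir152 at 0.17 (SE 0.04), Mir322-2 at 0.19 (SE 0.05) and ENSRNOG00000066772 at 0.26 (SE 0.06). Mir802 stood at 80488 ± 5605 FPKM (SD, n = 3) in Control, 103020 ± 6348 in CAF, 84404 ± 2354 in DEX and 98487 ± 15170 in CAF+DEX.

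Leukocyte microRNAs were lower with caffeine, and the mean of the 6 differed by -0.338 (exact two-sided permutation p = 0.01, smallest possible 0.005), which does not pass when adjusted over the 16 lists (Benjamini-Hochberg 0.08); no list passes, and the regulators of cytochrome P450 and nuclear receptor transcripts had a smaller p of 0.005 and muscle markers a larger difference of -0.511. The count of called features in the caffeine main effect was reached by 2 of 100 splits, the real one included (real 2, highest other 2). This share is small, but another split gave as many calls and several contrasts were split, so chance is not excluded. A leukocyte p as small came in 2 of 100 splits, again with the real one included. Scaling is argued against by the median in CAF against Control, which was -0.428 under the scaling that left it nearest 0. After thinning to equal reads the median was -0.494. Thinning draws reads evenly and the values are scaled to the total, so it could hardly have moved the median and does not decide on depth. With the erythroid mean as a covariate the caffeine effect moved from -0.338 (SE 0.076) to -0.204 (SE 0.070). The 3 erythroid microRNAs measure blood with error, so an effect can remain even if blood were the whole cause. Less blood in the tissue piece therefore stays open, as a part or as the whole. Fewer leukocytes in the tissue piece, or a lower level per cell, may account for the lower leukocyte microRNAs and stay open. In CAF+DEX against DEX the 6 had a median of -0.193, while endothelial, stellate and biliary lists had 0.099, 0.064 and 0.069. But neuron and pancreas, erythroid and muscle lists had -0.270, -0.227 and -0.095 (muscle mean -0.312). Mir155 and Mir223, chosen after their values were seen, lay at -0.03 and -0.01. The leukocyte list's call was lost in 6 of the leave-one-out fits (median -0.106 without DEX library 2).

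Both miR-29b copies were higher in each treated group than in Control, with a treated minus control difference for Mir29b1 of 0.216 (SE 0.042, limma adjusted p = 0.0215, 9 libraries against 3). The median-of-ratios difference was 0.221, which argues against scaling to the listed total. Chance low values in the 3 shared control libraries may account for it. Of 100 splits into 9 and 3 libraries, 11, the real one included, gave a feature with an absolute moderated t as large as the real 5.15, up to 6.54. Other splits can also carry the caffeine difference, so this share is not one of chance alone. The copies share reads and give 1 signal, and an effect of the drugs stays open and untested.

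The 10 splits of 6 libraries in a pairwise comparison are too few for a share under 0.05. The real and highest other counts of called features were 2 and 0 in CAF against Control and 0 and 0 in the other 4 pairwise comparisons. For called lists they were 2 and 5 in CAF against Control, 1 and 2 in DEX against Control, 2 and 5 in CAF+DEX against Control, 2 and 4 in CAF+DEX against CAF and 1 and 3 in CAF+DEX against DEX, with as many as the real count in 6 of 10 splits each. Chance is not excluded for the F test, where 11 of 100 splits gave as many features as the real 1 (highest other 2). Splits decide nothing for the 0 features of the interaction and of the dextromethorphan main effect, since each of 100 splits reaches 0 (highest other 2 each). Nor is chance excluded for lists, where 36 splits gave as many as the 2 of the caffeine main effect (highest other 4), 40 as many as the 2 of dextromethorphan (highest other 4) and 68 as many as the 1 of the interaction (highest other 5). The interaction splits mix libraries with and without caffeine, so their share does not measure chance for the interaction alone. All these counts of splits include the real one.

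The caffeine contrasts with and without dextromethorphan share no library. Their log2 fold changes had a Pearson correlation across features of 0.023 over all 293 and 0.355 over the 135 averaging at least 100 reads; features are not independent replicates.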
